A study of Mus musculus with 16 samples.

How the data were processed

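RNA from the colon of Swiss Webster mice, an outbred stock, was measured on Affymetrix Mouse Exon ST arrays in 16 samples: 4 from germ-free mice monocolonised with Bifidobacterium UCC2003, 4 from germ-free mice monocolonised with its TadA mutant, 4 from germ-free controls (GF) and 4 from re-conventionalised germ-free mice (CONV). The design text states 5 CONV animals, of which 4 have arrays used here. Groups were taken from the treatment label of each sample and replicates from its title. The number of arrays per group limits the precision of every value.

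The array values are log2 intensities that the authors normalised with RMA in Affymetrix Expression Console 1.1 on mm9, per the submitters' processing notes, which also name Partek. They cover 23332 transcript clusters, the probe groups that an exon array reads as 1 transcript. The authors' deposited comparison table covers 16135 of these features and gives log2 group means, each signed fold of the second group over the first, and each p-value with its Benjamini-Hochberg adjusted p-value from an ANOVA by the authors. A gene-level table that the authors deposited gives log2 values per array for 1793 genes, the p-value of the authors' ANOVA over the UCC2003, TadA mutant and GF arrays, and the ratio of the mean log2 value of the UCC2003 group to that of the TadA mutant group. The design text names Subio Platform for such analyses. All 1793 genes had a deposited p-value under 0.05, so this table holds genes chosen on these same arrays. A plain F test on its values gave a p under 0.05 for 1383 of them, with a median absolute difference of 0.172 and a largest of 3.54 in log10 p from the deposited p-value. The deposited ratio equalled the ratio of mean log2 values, within 0.001, in all 1793 genes, and is not a fold change. Columns of the gene-level table carry the group but not the replicate, so its values were assigned to groups only.

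Array medians ran from 5.91 to 6.03 log2 units, pairwise array correlations from 0.938 to 0.979, and 0 pairs of arrays were duplicates. The group means in the authors' deposited table differed from the means of the array values by a median of 0.0240 log2 units in UCC2003, 0.0245 in TadA mutant, 0.0253 in GF and 0.0744 in CONV, with a largest difference of 1.52 in CONV.

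A linear model with 1 coefficient per group was fitted to the log2 values of all 16 arrays with limma 3.58.1 in R 4.3.3, and each pair of groups was compared with the moderated test of limma (prior degrees of freedom 2.22), two-sided. The p-values were adjusted by Benjamini-Hochberg over the 23332 clusters, with a threshold of 0.05. Moderated F tests compared the 4 groups over 16 arrays, and the 3 groups without CONV over 12 arrays. The same model was fitted to the gene-level table. Because its genes had passed an ANOVA at 0.05, their p-values were adjusted over 35860 tests, the number of genes that a pass rate of 0.05 would need to leave 1793. This adjustment was chosen after the table had been seen, and the counts adjusted over the table's genes alone stand in the closing section. The 3 comparisons with GF share the same 4 GF arrays. Tested on simulated data with 100 clusters changed by each of 2 sizes, the procedure recovered 65 of 100 changes of log2 1 and 90 of 100 of log2 2, all with the right sign, and called 10 unchanged clusters. The simulated noise was independent between clusters, and more clusters were changed than were called in any comparison without CONV. These rates therefore do not give the recovery in those comparisons.

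The comparison table names a gene for few clusters: 1973 clusters had exactly 1 symbol (1964 distinct symbols), 61 had several and 5 had a symbol without a readable assignment. The others have no name here. Of the symbols, 1904 were found in the reference gene table, 102 of them under a newer symbol. Genes are named by a rule set before the data were examined, as were the comparisons, the gene lists and most alternatives. In UCC2003 against GF, TadA mutant against GF, UCC2003 against TadA mutant and CONV against GF, the rule takes the 10 largest rises and the 10 largest falls among the called clusters with 1 symbol, or the 10 smallest p-values where fewer than 5 passed. It adds up to 4 members of each described list by p-value, and Mki67, Lgr5, Muc2, Reg3b, Reg3g, Ang4 and Retnlb. Of these 7, only Retnlb had a named value, in the gene-level table, and the other 6 were not analysed here. Predicted and clone-named genes are counted and, with exceptions stated where they occur, not named. The rule was applied to the gene-level table in the same way.

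Of 33 gene lists, 13 had at least 3 measured members among the clusters: proliferation, goblet cell, enteroendocrine cell, antimicrobial and oxidant defence, interferon response, NF-kappaB and Toll-like receptor signalling, T and NK cell, smooth muscle, pancreas and small intestine, immediate early and heat shock, xenobiotic metabolism, tight junction, and mucin glycosylation. As many lists, 13, had at least 3 members in the gene-level table, among them absorptive colonocyte, antigen presentation, B cell, macrophage and dendritic cell, mast cell, and fibroblast and matrix. A further list of that table is not reported here. The lists of crypt stem cell and Wnt targets and of epithelial growth factors and receptors had fewer members in both and were not tested as lists. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, using the brightest cluster of each symbol. The same test with an estimated correlation, and limma's fry, were run beside it. In the gene-level table camera sets a list against the other genes of that table. These were chosen on the same arrays, so its p-values there are not those of an ordinary list test. The level of a list in an array is the mean over its members of the value minus the member's mean over all 16 arrays. List levels of 2 groups were compared with two-sided exact permutation tests over all 70 splits, a step chosen after the values had been seen.

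Arrays with pancreatic transcripts were those whose mean level of Cpa1 and Cel lay above the middle of its range over the 16 arrays. Alternatives were an ordinary fit without moderation, moderation with a trend and robust prior, array weights, median centring, quantile normalisation, a filter on the dimmest 40% of clusters, clusters with 1 symbol only, the replicate number as a block, the smooth muscle level as a covariate, fits without CONV or with the compared groups only, each array left out in turn, an unadjusted p under 0.05 with a 1.5-fold change, and the other list tests. After seeing the data, the Cpa1 and Cel level as a covariate, a fit without the arrays above, and the fits of the gene-level table were added. The correlation of the UCC2003 and TadA mutant changes was compared with 100 simulations of unchanged groups that share controls. Gene-level sheets at smaller p-values, which hold subsets of the sheet used, were left out. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.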

Results

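Colon gene expression was compared in germ-free Swiss Webster mice (GF), germ-free mice carrying only Bifidobacterium UCC2003, germ-free mice carrying only a UCC2003 strain with a mutated TadA gene, and germ-free mice given a conventional microbiota (CONV), with 4 arrays per group. TadA belongs to the bacterial locus for tight adherence pili, and the series title asks whether a protein associated with that pilus signals growth of the colonic epithelium. Values were log2 intensities for 23332 transcript clusters, 1973 of which could be assigned to exactly 1 gene, and for 1793 genes of a table that the authors had selected on the UCC2003, TadA mutant and GF arrays. That selection makes counts and list tests from the gene-level table no independent evidence of a difference between those 3 groups. The number of arrays limits the precision of every value.

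Pancreatic transcripts were abundant in part of the arrays of every group. Cpa1, a pancreatic carboxypeptidase, and Cel, a pancreatic lipase, were high in 8 of 16 arrays: 3 of the GF group, 2 of the UCC2003 group, 1 of the TadA mutant group and 2 of the CONV group. Cpa1 had a median of 13.11 log2 units in these arrays and 5.02 in the others. The lowest Cpa1 value among the former was 10.92, in CONV replicate 2, and the highest among the latter was 7.49, in TadA mutant replicate 4. Within groups, the largest axis of variation over all clusters (first principal component of the values minus their group means) held 22.3% of the variance. Its absolute correlation with the Cpa1 and Cel level was 0.894, so the variation that went with these transcripts was not limited to a few pancreatic genes. The list of pancreas and small intestine genes had a mean log2 difference from GF of -1.42 in UCC2003, -2.33 in TadA mutant and -1.71 in CONV, none of which passed the list test (adjusted p = 0.464, 0.273 and 0.381). Leaving out 1 array moved these means by more than 1.5 times: from -2.73 without GF replicate 1 to -0.44 without UCC2003 replicate 4, from -3.64 without GF replicate 1 to -1.71 without TadA mutant replicate 1, and from -3.02 without GF replicate 1 to -0.96 without CONV replicate 1.

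**Figure D1:**
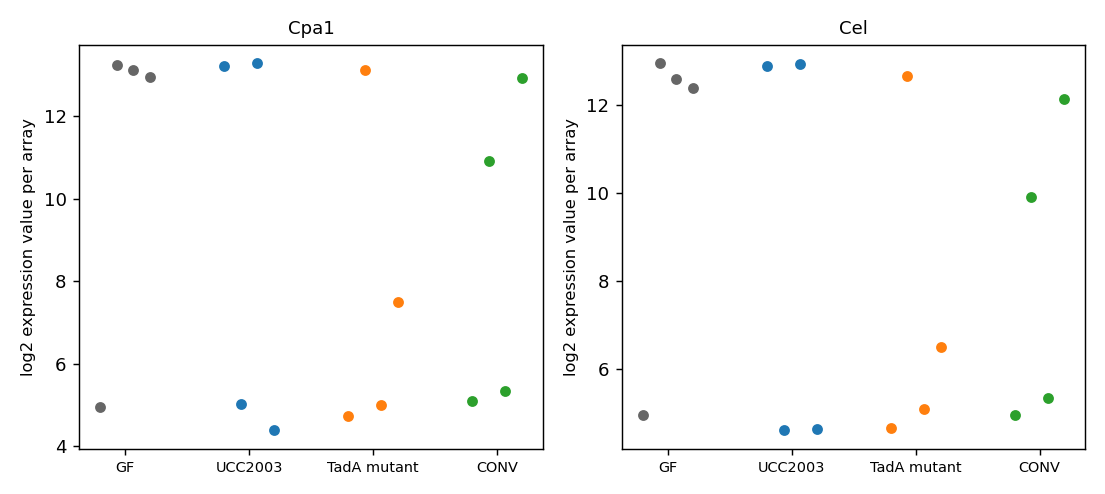
Log2 expression value of Cpa1 and Cel in each of the 16 arrays, by group (points are arrays, 4 per group). In 8 arrays, spread over all 4 groups, Cpa1 lies at 10.92 or more, and in the other 8 at 7.49 or less.

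The first question was what the parent strain changes in a germ-free colon. Retnlb, which encodes a resistin-like protein secreted by goblet cells, had a value only in the gene-level table, whose genes were selected on these arrays. There it rose in UCC2003 mice by 3.70 ± 0.26 log2 units (SE) over GF, from 6.91 ± 0.50 to 10.61 ± 0.36 (SD, n = 4 each). Its p adjusted over 35860 tests was 9.15e-06, and all 4 UCC2003 arrays lay above every GF array. B4galnt2, on chromosome 11, encodes a glycosyltransferase that adds N-acetylgalactosamine to glycans of the gut epithelium. Its value was 7.37 ± 0.20 in GF and 5.15 ± 0.35 in UCC2003 (SD, n = 4 each). It fell by 2.22 ± 0.29 log2 units (SE, 4.66-fold, adjusted p = 0.0209), with all 4 UCC2003 arrays below every GF array. Olfr323, an olfactory receptor gene, rose by 1.32 ± 0.19 log2 units (adjusted p = 0.0321), a call lost in 18 of 28 alternatives (adjusted p up to 0.343), among them median centring, the compared groups only, and leaving out any UCC2003 array, GF replicate 1, 2 or 4, TadA mutant replicate 4 or CONV replicate 1 or 2. Cnga1, a channel subunit known from photoreceptors, fell by 1.17 ± 0.16 log2 units in the gene-level table (adjusted p = 0.0210). That call was lost in 7 of 19 alternatives (adjusted p up to 0.129), namely the ordinary fit, the trend with a robust prior, and without UCC2003 column 1 or 4 or GF column 1, 3 or 4.

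By limma, 5 of 23332 clusters were called in UCC2003 against GF, 4 higher and 1 lower (1857 at an unadjusted p under 0.05), and 5 genes of the gene-level table, 3 higher and 2 lower. Of the 5 clusters, 3 have no gene name here. The largest change among them, in cluster 6841363, singled out after its values were seen, was 4.32 ± 0.27 log2 units (adjusted p = 3.84e-06). It is high in the same 2 groups as Retnlb, and whether the 2 measure the same transcript was not tested. For this pair of groups, 1 feature of the authors' deposited table had an adjusted p under 0.05, and B4galnt2 had an adjusted p of 0.111. The call of B4galnt2 ended when any GF array was left out, and without UCC2003 replicate 3 or 4, with adjusted p between 0.0547 and 0.0868. It ended in the ordinary fit (adjusted p = 0.110) and with the smooth muscle level as a covariate, where the difference was -2.24 and the SE widened from 0.29 to 0.44 (adjusted p = 0.887). It also ended without the arrays that carried pancreatic transcripts, which left 1 GF and 2 UCC2003 arrays and widened the SE (-2.02 ± 0.52, adjusted p = 0.508), a fit that called 0 clusters by limma (2033 at an unadjusted p under 0.05). The count of 5 clusters was 1 in the ordinary fit and with the smooth muscle covariate, and 2 with the compared groups only. It fell to 1 without GF replicate 2, GF replicate 4 or UCC2003 replicate 3, to 2 without GF replicate 1, CONV replicate 1 or CONV replicate 2, and to 3 without UCC2003 replicate 1 or 4.

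**Figure D2:**
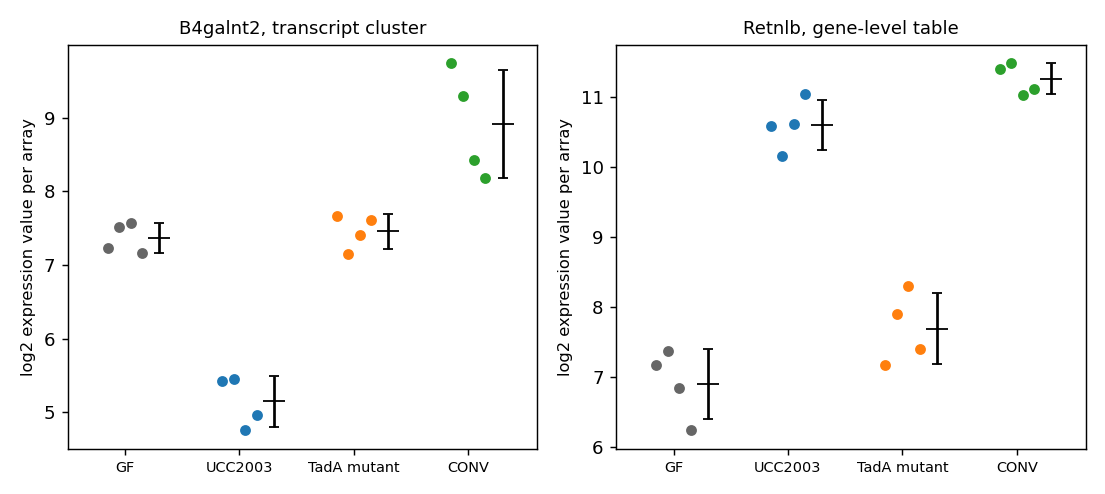
Log2 expression value of B4galnt2 (transcript cluster) and Retnlb (gene-level table) per array in the 4 groups, with the mean and SD as black bars (n = 4 each). B4galnt2 lies between 4.75 and 5.45 in UCC2003 and at 7.14 or more in every other array. Retnlb lies at 10.17 or more in UCC2003 and CONV and at 8.30 or less in GF and TadA mutant arrays.

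Among gene groups, smooth muscle was the only one of 13 tested on clusters that passed in UCC2003 against GF. Its 3 measured members were higher, with Lmod1 at 0.57 ± 0.15, Cnn1, a calponin of contractile cells, at 0.45 ± 0.14 and Tpm2, a tropomyosin, at 0.40 ± 0.12 log2 units (SE). None of the 3 passed over all clusters, and 3 passed when adjusted over the list alone. The list had an adjusted p of 0.000324, and an adjusted p = 0.287 with an estimated correlation. The mean list level differed by 0.47 log2 units (exact permutation p = 0.0286, two-sided, the smallest that 70 splits allow). All 6 smooth muscle genes of the gene-level table were higher (adjusted p = 0.00151), with Myl9, a myosin light chain, at 1.09 ± 0.19 (adjusted p = 0.117), and 6 passed when adjusted over the list alone, which is not independent evidence. With an estimated correlation the list had adjusted p = 0.235. Arrays with pancreatic transcripts numbered 2 in UCC2003 and 3 in GF.

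Goblet cell and interferon response members on clusters were higher in UCC2003 than in GF (4 of 4, but 3 with quantile normalisation, and 5 of 5), with list adjusted p of 0.464 and 0.588. The interferon difference of 0.22 log2 units rests on UCC2003 replicate 4, and without it was -0.053. For proliferation, 2 of 5 clusters were higher and 3 lower, and of 12 gene-level genes 5 were higher and 7 lower (adjusted p = 0.961 and 0.900). The mean of the 5 clusters was 0.022, but -0.012 with each array centred on its median and -0.034 with quantile normalisation, and their median was -0.04. Leaving out 1 array moved this mean between -0.061 and 0.089, with a changed sign without UCC2003 replicate 1 or 4 or GF replicate 4. Mucin glycosylation had 1 called member, B4galnt2, and an adjusted p of 0.532 as a list, with a mean of -0.62 and a median of 0.11. The other lists on clusters had an adjusted p between 0.464 (pancreas and small intestine) and 0.873.

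A further 4 lists of the gene-level table passed in UCC2003 against GF, on genes that the authors chose on these arrays. Neither the counts nor the list p-values are therefore independent evidence. B cell genes were higher in 7 of 7 members by a mean of 0.76 log2 units (adjusted p = 0.00363, and adjusted p = 0.235 with an estimated correlation), with Cd79b, a part of the B cell receptor, at 1.00 ± 0.25, and 5 passed when adjusted over the list alone. Antigen presentation was higher in 6 of 7 by a mean of 0.49 (adjusted p = 0.0306, and adjusted p = 0.235 with an estimated correlation), with H2-Ab1 at 0.65 ± 0.20 and 4 passing when adjusted over the list alone. Fibroblast and matrix genes were higher in 4 of 4 by a mean of 0.42 (adjusted p = 0.0306, and adjusted p = 0.235 with an estimated correlation), with the fibronectin gene Fn1 at 0.60 ± 0.14 and 3 passing when adjusted over the list alone. Enteroendocrine genes were lower in 3 of 3 by a mean of -0.58 (adjusted p = 0.0306, and adjusted p = 0.235 with an estimated correlation), with the glucagon gene Gcg at -0.84 ± 0.16 and 3 passing when adjusted over the list alone. None of the members of these 4 lists passed over all tests (0 by limma).

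The second question was what the TadA mutant changes. No cluster was called by limma in TadA mutant against GF (0 of 23332), with 1403 at an unadjusted p under 0.05 and a smallest adjusted p of 0.346. The fit without moderation also called 0, and the authors' deposited table has 0 features with an adjusted p under 0.05 (938 unadjusted). Without UCC2003 replicate 3, which enters only the shared estimate of spread, 1 cluster passed. The smallest p-values among named clusters belonged to S1pr4, a sphingosine phosphate receptor of lymphoid cells, at -0.83 ± 0.15 log2 units (SE, adjusted p = 0.422), H2-M2, a class Ib histocompatibility gene, at 0.56 ± 0.13, and the mast cell protease gene Mcpt1 at 0.63 ± 0.15 (adjusted p = 0.748 for both). Of the gene-level genes, 0 were called by limma (740 at an unadjusted p under 0.05). There Igf2, a growth factor gene, was at -0.71 ± 0.13 (adjusted p = 0.420), and Csf2, a myeloid growth factor gene, at 0.77 ± 0.15 (adjusted p = 0.497). Retnlb was at 0.79 ± 0.26 (adjusted p = 1) and B4galnt2 on clusters at 0.09 ± 0.29 (adjusted p = 0.963).

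The smooth muscle list passed in TadA mutant against GF too, with 3 of 3 clusters higher by a mean of 0.41 log2 units (adjusted p = 0.000681). It had adjusted p = 0.349 with an estimated correlation, and 3 members passed when adjusted over the list alone. Its level had an exact permutation p of 0.0571 (two-sided). The proliferation list, with 5 of 5 members higher, had a mean of 0.25 log2 units, an adjusted p of 0.0474 and an exact permutation p of its level of 0.0571 (two-sided). With an estimated correlation it had adjusted p = 0.430, and 0 of its members passed when adjusted over the list alone (limma). Birc5, an inhibitor of apoptosis expressed in mitosis, was at 0.36 ± 0.19 and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at 0.38 ± 0.21. Of the gene-level proliferation genes, 12 of 12 were higher (adjusted p = 0.000607, and adjusted p = 0.373 with an estimated correlation), led by the spindle checkpoint kinase gene Bub1b at 0.73 ± 0.19 and Nusap1, a spindle protein gene, at 0.53 ± 0.16. Adjusted over the list alone, 7 passed, which is not independent evidence because the authors chose the genes on these arrays. Antigen presentation (7 of 7 higher, mean 0.76, adjusted p = 0.000607), B cell (7 of 7, mean 0.78, adjusted p = 0.00143), fibroblast and matrix (4 of 4, mean 0.51, adjusted p = 0.00714) and smooth muscle genes (6 of 6, mean 0.43, adjusted p = 0.0193) passed there as well, each with adjusted p = 0.246 with an estimated correlation. Adjusted over the list alone, 7, 6, 4 and 5 of their members passed. The other lists on clusters had an adjusted p between 0.227 and 0.997. Arrays with pancreatic transcripts numbered 1 in the TadA mutant group and 3 in the GF group.

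The direct comparison of the parent strain with the TadA mutant asks what differs when the TadA gene is mutated. The labels used here give treatment and replicate but no litter or cage. A difference between the groups in these cannot be told apart from the TadA gene, for any gene or list below. In the gene-level table, selected on these arrays, Retnlb was higher by 2.91 ± 0.26 log2 units (SE, 7.54-fold) in UCC2003 than in TadA mutant mice. The mean of the latter was 7.69 ± 0.51 (SD, n = 4). The adjusted p was 0.000284, with all 4 UCC2003 arrays above every TadA mutant array. On clusters B4galnt2 was lower by a log2 difference of -2.31 ± 0.29 (SE, 4.95-fold, adjusted p = 0.0132), with TadA mutant arrays at 7.46 ± 0.24 (SD, n = 4) and all 4 UCC2003 arrays below them. The gene-level value of B4galnt2 differed by -2.18 ± 0.28 (adjusted p = 0.0126). The other gene-level calls were the predicted genes Gm609 at 1.91 (adjusted p = 0.0102) and Gm20519 at -0.91 (adjusted p = 0.0180), named after their values were seen because the count was small.

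By limma 2 of 23332 clusters were called in UCC2003 against TadA mutant (835 at an unadjusted p under 0.05). They were B4galnt2 and cluster 6841363, which has no gene name here and was higher by 3.44 ± 0.27 log2 units (adjusted p = 7.97e-05). The authors' deposited table has 0 features with an adjusted p under 0.05 for this pair (618 unadjusted), and B4galnt2 there had a p of 1.75e-05 and an adjusted p of 0.142. Leaving out TadA mutant replicate 1, 3 or 4 left 1 cluster, and B4galnt2 then had adjusted p of 0.0903, 0.0668 and 0.0770. Without UCC2003 replicate 3 or 4 it had 0.0560 and 0.0597, and in the ordinary fit 0.0816. Without the arrays with pancreatic transcripts, the difference in B4galnt2 was -2.35 ± 0.39 with an adjusted p of 0.634, and 0 clusters were called by limma (1351 at an unadjusted p under 0.05). The gene-level count of 4 fell to 1 without column 1 of the TadA mutant group and to 2 without column 4 of the UCC2003 group. Cyp4f14, a cytochrome P450 gene, was at 1.05 ± 0.18 (adjusted p = 0.202) and Nqo1, a quinone reductase gene, at -0.74 ± 0.18 (adjusted p = 1.00).

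Proliferation genes were lower in UCC2003 than in TadA mutant arrays: 5 of 5 clusters, by a mean of -0.23 log2 units, with Ube2c at -0.45 ± 0.21 and Birc5 at -0.40 ± 0.19. The list had an adjusted p of 0.0350, and adjusted p = 0.452 with an estimated correlation. None of the 5 passed over all clusters, and 0 passed when adjusted over the list alone (limma, 1 at an unadjusted p under 0.05). The list level had an exact permutation p of 0.0286 (two-sided). Of the gene-level members, 12 of 12 were lower (adjusted p = 0.000934), with Cenpf, a kinetochore protein gene, at -0.58 ± 0.15 and Bub1b at -0.60 ± 0.19. Adjusted over the list alone 6 passed, which is not independent evidence, and with an estimated correlation the list had adjusted p = 0.411. The enteroendocrine list in the gene-level table was lower in 3 of 3 members, the hormone genes Insl5 at -0.75 ± 0.14, Gcg at -0.56 ± 0.16 and Pyy at -0.42 ± 0.10. It had an adjusted p of 0.00944, with 3 passing when adjusted over the list alone, which is not independent evidence, and adjusted p = 0.184 with an estimated correlation. On clusters that list had 3 of 4 members lower and an adjusted p of 0.316. Among the other lists on clusters, immediate early and heat shock genes were higher in 4 of 4 members (adjusted p = 0.284), and xenobiotic metabolism had 1 of 3 higher (adjusted p = 0.316). The remaining lists had an adjusted p between 0.316 and 0.917. Arrays with pancreatic transcripts numbered 2 in UCC2003 and 1 in TadA mutant.

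**Figure D3:**
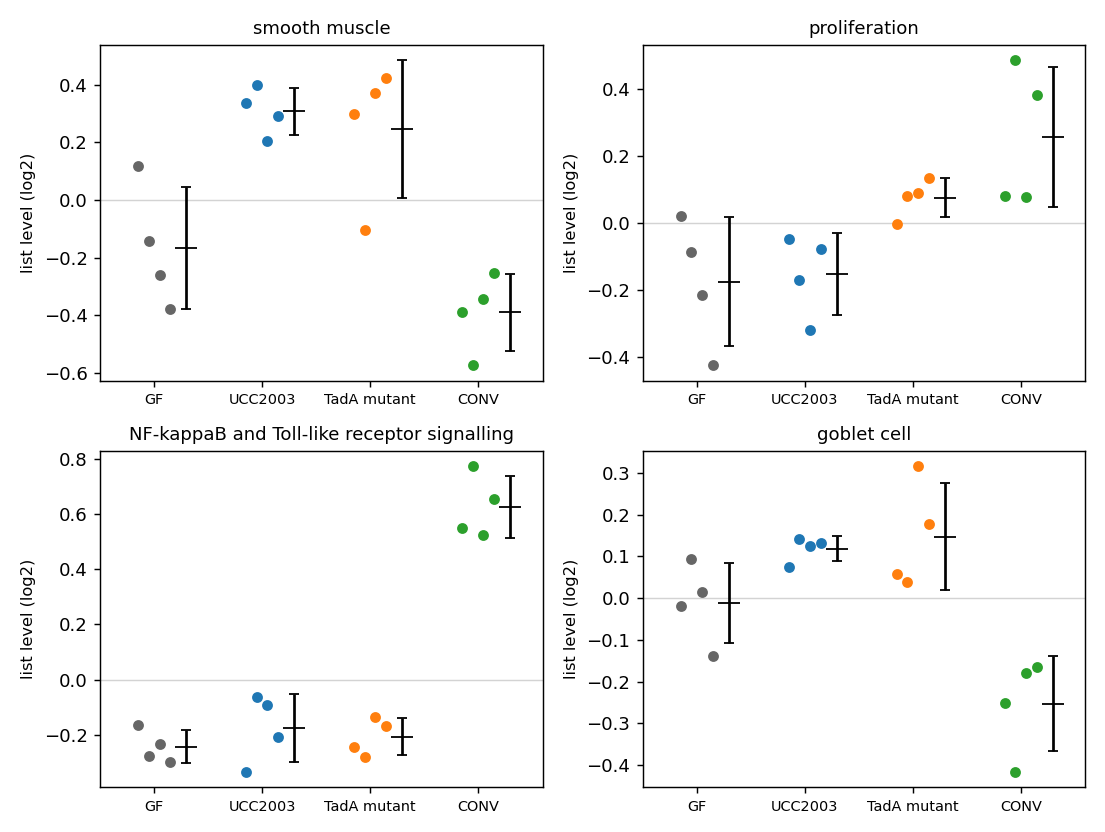
Level of 4 gene lists in each array (mean over list members of the log2 value minus the member's mean over 16 arrays), by group, with the mean and SD as black bars (n = 4 each). The smooth muscle level averages 0.31 in UCC2003 and -0.17 in GF, and the NF-kappaB and Toll-like receptor level averages 0.63 in CONV and lies below 0 in every other array.

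Re-conventionalised mice served as the reference for a full microbiota. Among the named clusters, Tnf, an inflammatory cytokine gene, rose in CONV over GF by 1.86 ± 0.15 log2 units (SE, adjusted p = 1.46e-05), Cxcl9, an interferon-induced chemokine gene, by 2.07 ± 0.22, and Tnfsf10, a death ligand gene, by 2.25 ± 0.22. The largest rise on named clusters was that of Sprr1a, a small proline-rich protein gene of stressed epithelium, by 2.64 ± 0.33. Aqp4, a water channel gene, rose by 2.34 ± 0.18, and Slc51b, a subunit of the basolateral bile acid exporter, by 1.94 ± 0.22. On the gene level Retnlb rose by 4.36 ± 0.26 (20.5-fold, adjusted p = 2.82e-07), Duox2, which makes hydrogen peroxide at the epithelial surface, by 2.61 ± 0.24, and Gvin1, an interferon-induced GTPase gene, by 2.79 ± 0.29. Fxyd4, a regulator of the sodium pump in the colon, fell by 4.08 ± 0.25 (adjusted p = 2.82e-07). Further falls on clusters were those of Best2, an anion channel gene of colonic goblet cells, by 0.92 ± 0.15, Suox, sulfite oxidase, by 0.92 ± 0.14, and Klb, the co-receptor beta-klotho, by 0.71 ± 0.15. The call of Klb was lost in 8 of 28 alternatives (adjusted p up to 0.527), among them leaving out GF replicate 2 or 3 or CONV replicate 2 or 3, and that of Suox in 2 of 28. Without the arrays with pancreatic transcripts, the calls of Tnf, Cxcl9, Tnfsf10, Sprr1a, Aqp4, Slc51b and Best2 were lost too (adjusted p = 0.237, 0.320, 0.191, 0.229, 0.137, 0.237 and 0.406), their only loss in 28 alternatives. B4galnt2 rose by 1.55 ± 0.29 on clusters (adjusted p = 0.0113), a call lost in 2 of 28 alternatives, with the compared groups only (adjusted p = 0.127) and without the arrays with pancreatic transcripts (0.429), and its gene-level value of 1.48 ± 0.28 had an adjusted p of 0.05001 and was not called.

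By limma 440 of 23332 clusters were called in CONV against GF, 329 higher and 111 lower (3071 at an unadjusted p under 0.05), of which 57 have a single gene symbol, 45 higher and 12 lower. The 20 clusters named by rule ranged from 1.76 to 2.64 log2 units among the rises and from -1.09 to -0.52 among the falls. The largest of these falls, in Eci3, lost its call in 12 of 28 alternatives (adjusted p up to 0.225), among them leaving out GF replicate 1, 2 or 3, CONV replicate 1, 2 or 3 or TadA mutant replicate 1. A count of 62 gene-level genes was called, 49 higher and 13 lower. The authors' deposited table, over 16135 features, has 290 with an adjusted p under 0.05 for this pair. Its CONV means differed from those of the arrays by up to 1.52 log2 units, so the 2 counts are not directly comparable. The count of 440 fell to 241 without CONV replicate 2, 278 without GF replicate 1, 282 without GF replicate 2 and 279 without GF replicate 3. It was 112 with the compared groups only and 267 with the smooth muscle level as a covariate. Without the arrays with pancreatic transcripts, which left 1 GF and 2 CONV arrays, it was 3.

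**Figure D4:**
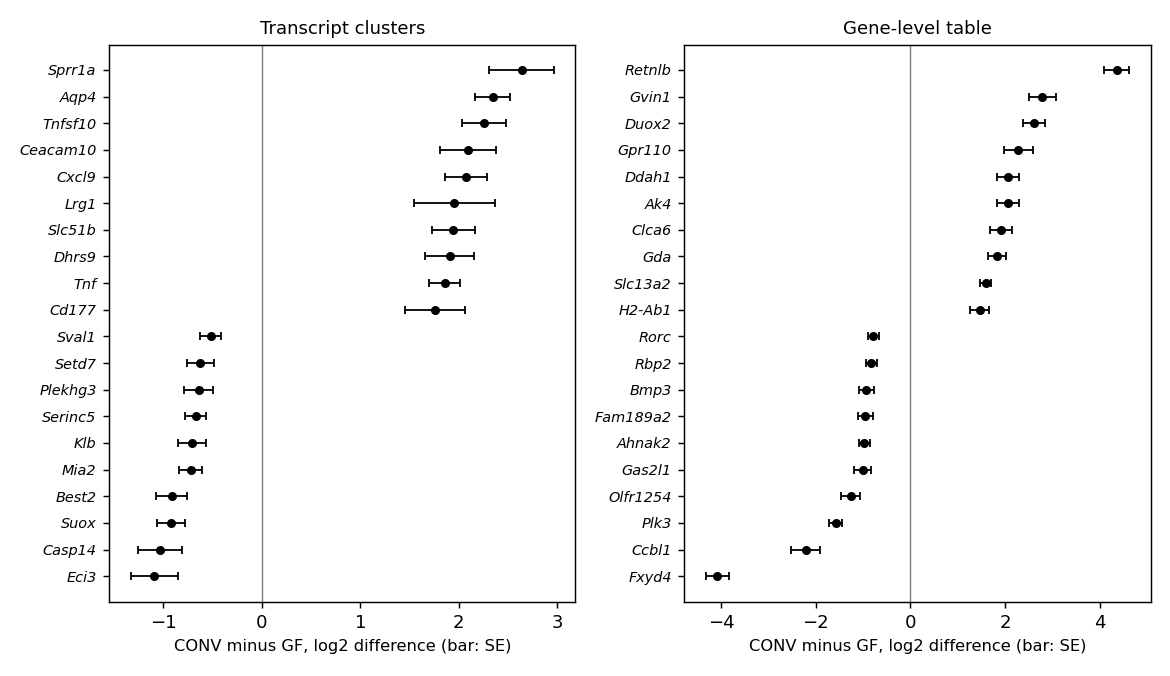
Log2 difference of CONV minus GF for the named clusters (20) and the named genes of the gene-level table (20), with the SE as bars (n = 4 arrays per group). Sprr1a at 2.64 and Retnlb at 4.36 are the largest rises, and Eci3 at -1.09 and Fxyd4 at -4.08 the largest falls shown.

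Of the gene lists on clusters, 5 passed in CONV against GF. NF-kappaB and Toll-like receptor signalling rose (adjusted p = 6.49e-05, and adjusted p = 0.0162 with an estimated correlation). Of its 5 members, 3 rose: Cd14, a co-receptor for lipopolysaccharide, by 1.67 ± 0.12 log2 units, Tnf, and Tlr2, a receptor for bacterial lipoproteins, by 0.81 ± 0.17. The same 3 passed when adjusted over the list alone. The call of Tlr2 was lost in 8 of 28 alternatives (log2 down to 0.36, adjusted p up to 0.757), among them array weights and leaving out GF replicate 2, 3 or 4 or CONV replicate 2 or 4. Of 7 antimicrobial and oxidant defence genes, Sprr1a and Nox1, an epithelial NADPH oxidase gene (1.45 ± 0.23), rose, Reg4 fell by 0.44 ± 0.08, and 4 did not pass (list adjusted p = 0.0361, and adjusted p = 0.197 with an estimated correlation). The call of Reg4 was lost in 4 of 28 alternatives, among them without GF replicate 1 (adjusted p up to 0.515). The interferon response list was higher in 5 of 5 members with Cxcl9 called (adjusted p = 0.00992, and adjusted p = 0.197 with an estimated correlation). Proliferation was higher in 4 of 5, with Ube2c at 0.77 ± 0.21 and Birc5 at 0.74 ± 0.19, 0 called by limma and 3 when adjusted over the list alone (list adjusted p = 0.0138, and adjusted p = 0.197 with an estimated correlation). Goblet cell genes were lower in 4 of 4 members with a named cluster, with the trefoil peptide gene Tff3 at -0.31 ± 0.10 and Zg16, a mucus lectin gene, at -0.20 ± 0.08. The list adjusted p was 0.0138, and adjusted p = 0.192 with an estimated correlation, with 0 called by limma and 1 when adjusted over the list alone. Retnlb, a member of the goblet cell list without a named cluster, was not in this test and rose in the gene-level table, as given above. Cldn23, a claudin gene, rose by 1.06 ± 0.16 in the tight junction list (list adjusted p = 0.109). Without the arrays with pancreatic transcripts, which left 1 GF array, the calls of Cd14, Nox1 and Cldn23 were lost. With the Cpa1 and Cel level as a covariate they were kept, at 1.65, 1.36 and 1.13 log2 units (limma, adjusted p = 2.41e-05, 0.00659 and 0.00154). Other lists had an adjusted p between 0.0923 (smooth muscle) and 0.793. Arrays with pancreatic transcripts numbered 2 in CONV and 3 in GF.

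Among gene-level genes, antigen presentation was higher in 7 of 7 members in CONV and 5 rose over all tests, among them H2-Ab1 by 1.47 ± 0.20 and H2-Aa by 1.19 ± 0.17, both class II histocompatibility genes, and Cd74, the invariant chain gene, by 1.43 ± 0.20. The list had an adjusted p of 3.99e-08, and adjusted p = 0.0452 with an estimated correlation, with 7 passing when adjusted over the list alone. Proliferation was higher in 12 of 12 (adjusted p = 1.07e-06, and adjusted p = 0.244 with an estimated correlation). Nusap1 rose by 0.93 ± 0.16, a call lost in 6 of 19 alternatives (adjusted p up to 0.144), among them without GF column 1 or CONV column 1, 2 or 4, Top2a was at 1.08 ± 0.23 (adjusted p = 0.112), and 12 passed when adjusted over the list alone. B cell genes were higher in 7 of 7, with Cd79b at 1.03 ± 0.25 (adjusted p = 0.0001665 for the list, and adjusted p = 0.244 with an estimated correlation), 0 called by limma and 7 when adjusted over the list alone. Macrophage and dendritic cell genes were higher in 3 of 3 (adjusted p = 0.00928, and adjusted p = 0.163 with an estimated correlation), and C1qb, a complement gene, rose by 0.55 ± 0.10 and Csf1r by 0.71 ± 0.13. The authors chose these genes on arrays that include the GF group, so the list counts and list p-values are not independent evidence. The gene-level call of Csf1r held in only 2 of 19 alternatives and that of C1qb in 6 of 19. On clusters C1qb rose by 0.889 log2 units (limma, adjusted p = 0.0101), a call that held in 26 of 28 alternatives.

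Against the colonised groups, 706 clusters were called in CONV against UCC2003, 324 higher and 382 lower, and 327 in CONV against TadA mutant, 197 higher and 130 lower (limma). With the smooth muscle level as a covariate 17 were called in each. The majority direction against UCC2003 depended on the scaling, with 432 higher and 384 lower when each array was centred on its median and 516 higher and 332 lower with quantile normalisation. Of the clusters called higher in CONV against GF, 218 were also called higher against UCC2003 (4.57 for independent calls) and 165 against TadA mutant (2.78), but these comparisons share the CONV arrays. NF-kappaB and Toll-like receptor signalling passed in both (adjusted p = 0.000151 and 7.71e-05), also with an estimated correlation (adjusted p = 0.0241 and 0.0217). Smooth muscle genes were lower in CONV in 3 of 3 members in both, by a mean of -0.70 and -0.64 log2 units (adjusted p = 0.000151 and 7.71e-05), with 2 called in each. With an estimated correlation these had adjusted p = 0.0937 and 0.0789. Goblet cell genes with a named cluster, which leave out Retnlb, were lower in 4 of 4 in both (adjusted p = 0.00216 and 0.000414, and with an estimated correlation adjusted p = 0.0705 and 0.0359). The proliferation list was higher in CONV than in UCC2003 (4 of 5 members, adjusted p = 0.0379, and adjusted p = 0.298 with an estimated correlation), and had an adjusted p of 0.369 against TadA mutant. Gene-level smooth muscle genes were lower in 6 of 6 members in both (adjusted p = 3.05e-06 and 5.62e-05, and with an estimated correlation adjusted p = 0.0476 and 0.1001). Antigen presentation was higher in both (adjusted p = 0.00206 and 0.0131, and with an estimated correlation adjusted p = 0.348 and 0.287), proliferation against UCC2003 (12 of 12, adjusted p = 9.72e-05, and adjusted p = 0.348 with an estimated correlation), and fibroblast and matrix genes were lower against TadA mutant (4 of 4, adjusted p = 0.0419, and adjusted p = 0.287 with an estimated correlation). The count of 706 fell to 306 without UCC2003 replicate 2, 316 without UCC2003 replicate 3, 360 without CONV replicate 2 and 398 without UCC2003 replicate 4. The count of 327 fell to 163, 169 and 180 without TadA mutant replicate 1, 3 and 4 and to 186 without CONV replicate 2. With the compared groups only the counts were 194 and 83, and without the arrays with pancreatic transcripts 7 and 29.

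Over all 4 groups the moderated F test called 381 clusters (3382 at an unadjusted p under 0.05), and over the 3 groups without CONV it called 2 (1555). The count of 381 fell to 183 without CONV replicate 2, 238 without UCC2003 replicate 3 and 245 without TadA mutant replicate 1. Without the arrays with pancreatic transcripts the counts were 4 and 0 (1643 of the latter at an unadjusted p under 0.05, limma).

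The last question was how far a single species moved the genes that a full microbiota moves. The changes of UCC2003 and TadA mutant from the shared GF arrays had a Pearson r of 0.614 across clusters, which are not independent replicates. Unchanged groups simulated against shared controls gave a mean r of 0.468, with 95% of values between 0.0815 and 0.787. With the GF arrays split into separate pairs, r lay between -0.0113 and 0.206 over 6 splits. Of the clusters called in CONV against 2 GF arrays (172.83 on average), 60.6% ± 3.72 had the same sign in UCC2003 against the other 2 GF arrays and 67.0% ± 4.33 in TadA mutant (SD over the 6 splits). The 6 splits reuse the same arrays, so this SD does not give the precision of the shares. The simulated share for unchanged groups was 48.7%, with 95% of values between 29.3% and 66.3%.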

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

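The tests of colonisation group, of a sequence variant under the probes of 1 gene, of a variant of the locus carried by the mice of 1 group and of the choice of genes by the authors' test were chosen after the result was seen, and the gene-level table was fitted only after it had been seen.

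The difference between UCC2003 and TadA mutant in their changes from GF was tested directly and passed for B4galnt2 (log2 difference -2.31, adjusted p = 0.0132, and -2.18 in the gene-level table, adjusted p = 0.0126), for cluster 6841363, which has no gene name here (3.44, adjusted p = 7.97e-05), and for Retnlb (2.91, adjusted p = 0.000284), Gm609 (1.91, adjusted p = 0.0102) and Gm20519 (-0.91, adjusted p = 0.0180) in the gene-level table. In UCC2003, 4 of 4 arrays lay beyond every TadA mutant array for B4galnt2 and Retnlb. Litter and cage, absent from the labels used here, cannot be told apart from the TadA gene for any of these differences. Cluster 6841363 was high in UCC2003 and CONV, as Retnlb was, and whether both measure the same transcript was not tested, so they are not counted as separate findings.

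Single arrays far from the other 3 of their group occurred in 31 of 576 groups of 4 arrays, 1.08 per 20, where chance gives about 1 in 20. On clusters they were Tppp in CONV replicate 1 (7.31, nearest 7.04), Cyp4f14 in TadA mutant replicate 4 (6.53, nearest 5.98), Pspn in GF replicate 2 (5.85, nearest 5.41), Olfr610 in UCC2003 replicate 3 (3.28, nearest 4.73), Olfr31 in UCC2003 replicate 2 (3.45, nearest 4.40), Casp14 in GF replicate 4 (6.62, nearest 6.86), Serinc5 in TadA mutant replicate 1 (7.70, nearest 7.78), Plekhg3 in UCC2003 replicate 1 (7.31, nearest 6.88) and C1qb in GF replicate 4 (5.79, nearest 6.62). Among list levels they were the enteroendocrine list in TadA mutant replicate 3 (-0.14, nearest 0.04), the antimicrobial list in UCC2003 replicate 4 (0.090, nearest -0.29), the pancreas and small intestine list in GF replicate 1 (-2.57, nearest 2.54) and the mucin glycosylation list in UCC2003 replicate 2 (-0.35, nearest -0.60).

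In the gene-level table, whose columns carry no replicate number, they were Cd79a (8.33), Cma1 (5.48), Gsta1 (10.08), Zfp248 (5.61), Ddah1 (9.81), Plk3 (7.30) and Olfr1254 (1.92) in 1 CONV column each, Cma1 (6.36), Kif11 (6.53) and Bmp3 (7.48) in 1 UCC2003 column each, Bub1b (5.53), Igf2 (5.40), Ahnak2 (7.465), Csf1r (6.88) and Ms4a1 (4.99) in 1 TadA mutant column each, and Nusap1 (4.78), Igf2 (5.89) and Csf1r (5.85) in 1 GF column each.

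Pancreatic transcripts were high in 8 of 16 arrays, and 4 of 4 groups hold both kinds of array, which argues against colonisation group as the whole cause. Arrays of pancreas in place of colon are argued against by 12 colon epithelial genes, whose mean within-group difference between arrays with and without these transcripts was -0.034 log2 units (from -0.29 to 0.21). Pancreatic tissue in the colon samples stays open as a candidate source: of 32 acinar genes listed before the test, 1 is named in the tables used (Rbpjl, median 7.03 against 5.37). It was higher in each array with high Cpa1 and Cel than in every other array, but narrowly (lowest 5.61 against highest 5.52). That is 1 of 1, too few genes to decide. Carry-over between samples in handling was not tested, and colonisation group was the only biological explanation tested.

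For B4galnt2, low in 4 of 4 UCC2003 arrays against every other array, pancreatic transcripts are argued against, since the UCC2003 minus TadA mutant difference was -2.27 ± 0.29 (SE, adjusted p = 0.0299) with the Cpa1 and Cel level as a covariate and -2.31 ± 0.29 without it. A sequence variant under the probes of 1 gene stays open: Gm11534, a gene of the same locus singled out after its values were seen, differed by -2.03 (adjusted p = 0.339), but a second gene that missed the threshold does not decide. A variant of the locus carried by the mice of 1 group also stays open, because Swiss Webster is an outbred stock, litters are not given in the labels, and 4 of 4 arrays on 1 side is what such a variant and an effect of the bacterium would both give. These 2 and the presence of the TadA gene in the bacterium cannot be told apart for B4galnt2 in these arrays.

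For proliferation genes, lower in UCC2003 than in TadA mutant, pancreatic transcripts are argued against (mean of the clusters -0.23 with the Cpa1 and Cel level as a covariate and -0.23 without). The choice of the listed genes by the authors' test stays open: the 4 clusters of the list outside the authors' table had a level difference of -0.17 with an exact permutation p of 0.0571 (two-sided), which misses the threshold but does not show that they did not differ. An effect of the TadA gene, which the design varies, stays open as well. It cannot be told apart from litter or cage, and chance was not excluded for the list count given below.

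Other splits of the arrays show whether a chance division of the arrays gives counts as large. In UCC2003 against GF 1 of 35 splits, the real one, gave as many clusters (5, highest other 1), and in UCC2003 against TadA mutant 1 of 35 (2, highest other 1). In CONV against GF it was 1 of 35 (440, highest other 4), in CONV against UCC2003 1 of 35 (706, highest other 1) and in CONV against TadA mutant 1 of 35 (327, highest other 3). These shares lie under 0.05 and are the smallest that 35 splits allow. They were not adjusted over the comparisons, so chance is unlikely for each count taken alone but is not excluded. The counts of 5 and 2 stand close to the highest other, unlike those with CONV. In TadA mutant against GF, 35 of 35 gave as many (0, highest other 2, limma, 1403 at an unadjusted p under 0.05, and 0 by the ordinary fit). For the F tests, 1 of 100 splits over the 4 groups, the real one, gave as many (381, highest other 329). Over the 3 groups it was 3 of 100 (2, highest other 3). Both shares lie under 0.05. Over the 3 groups a random split called more clusters than the real one, so chance is not excluded there.

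For lists, the share of splits was under 0.05 only in CONV against GF (1 of 35 splits, 5 lists, highest other 2), with the same limit. That share was above 0.05 in UCC2003 against GF (9 of 35, 1 list, highest other 2), TadA mutant against GF (3 of 35, 2 lists, highest other 2) and UCC2003 against TadA mutant (13 of 35, 1 list, highest other 2). It was also above 0.05 in CONV against UCC2003 (5 of 35, 4 lists, highest other 7) and CONV against TadA mutant (4 of 35, 3 lists, highest other 4). For the gene-level table the splits say nothing, because its genes were chosen on the real groups: 1 of 35 in UCC2003 against GF (5, highest other 0), 35 of 35 in TadA mutant against GF (0, highest other 0, limma, 740 at an unadjusted p under 0.05), 1 of 35 in UCC2003 against TadA mutant (4, highest other 0) and 1 of 35 in CONV against GF (62, highest other 0).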

How the results depend on the processing

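The covariate for pancreatic transcripts, the fit without the arrays that carry them, and the alternatives for the gene-level table were chosen after seeing the data, and the cause of a changed count was not tested unless stated.

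Counts moved by more than 1.5 times are given in the order of the comparisons. With the ordinary fit UCC2003 against GF had 1 and UCC2003 against TadA mutant 1, and for gene-level genes 1, 1 and, for CONV against GF, 40. Array weights gave 582 in CONV against TadA mutant and 8 genes of the gene-level table in UCC2003 against TadA mutant. A trend with a robust prior gave 3 genes of that table in UCC2003 against GF. Leaving out the dimmest 40% gave 3 in UCC2003 against GF, and 12 arrays without CONV gave 3. With single-symbol clusters only, which leaves fewer clusters to call, UCC2003 against GF had 2, CONV against GF 71, against UCC2003 109, against TadA mutant 59, the 4 groups 61, and the share of UCC2003 changes with the sign of CONV was 54.1%.

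With the replicate number as a block the counts were 2 in UCC2003 against GF, 293 in CONV against GF, 381 against UCC2003 and 196 over the 4 groups, and the share was 56.3%. The numbers do not pair the arrays: 24 pairs with the same number had a median r of -0.0442 and other pairs 0.0273. With the smooth muscle level as a covariate they were 1 in UCC2003 against GF, 267, 17 and 17 in CONV against GF, UCC2003 and TadA mutant, and 89 over the 4 groups, and the share was 53.6%. With the compared groups only, which leaves fewer arrays for the spread, they were 2 in UCC2003 against GF, 112, 194 and 83 in the CONV comparisons, and for gene-level genes 2 in UCC2003 against TadA mutant and 18 in CONV against GF.

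With the Cpa1 and Cel level as a covariate UCC2003 against GF had 3. Without the arrays with pancreatic transcripts, which leaves 8 arrays and 1 in GF, assumed to vary like the other groups, the counts were 0 in UCC2003 against GF and 0 against TadA mutant (limma, 2033 and 1351 at an unadjusted p under 0.05), 3, 7 and 29 in the CONV comparisons, 4 over the 4 groups, 0 over the 3 (limma, 1643 unadjusted), and 8 list calls. An unadjusted p under 0.05 with a 1.5-fold change gave 460, 350 and 288 in UCC2003 against GF, TadA mutant against GF and UCC2003 against TadA mutant, and 929, 1283 and 955 in CONV against GF, UCC2003 and TadA mutant. Lists called over the 6 comparisons numbered 16, and 4 with an estimated correlation. With fry they were 1, 0 and 0 in UCC2003 against GF, TadA mutant against GF and UCC2003 against TadA mutant, and 6, 10 and 6 in CONV against GF, UCC2003 and TadA mutant. Calls that ended with fry were smooth muscle and proliferation in TadA mutant against GF (adjusted p = 0.0861 and 0.324) and proliferation in UCC2003 against TadA mutant (0.291). Adjusted over the table's genes alone, the gene-level counts were 686, 230, 101 and 256, by the smaller number of tests.

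Leaving out each array gave 1 to 6 in UCC2003 against GF (1 without GF 2, GF 4 or UCC2003 3; 2 without GF 1, CONV 1 or CONV 2; 3 without UCC2003 1 or 4), 0 to 1 in TadA mutant against GF (1 without UCC2003 3), 1 to 3 in UCC2003 against TadA mutant (1 without TadA mutant 1, 3 or 4; 3 without GF 2), 241 to 454 in CONV against GF (241 without CONV 2, 278, 282 and 279 without GF 1, 2 and 3), 306 to 903 in CONV against UCC2003 (306, 316 and 398 without UCC2003 2, 3 and 4; 360 without CONV 2), 163 to 392 in CONV against TadA mutant (163, 169 and 180 without TadA mutant 1, 3 and 4; 186 without CONV 2), 183 to 364 over the 4 groups (183 without CONV 2, 238 without UCC2003 3, 245 without TadA mutant 1) and 2 to 3 over the 3 groups. The r of the 2 monocolonised changes ran from 0.495 to 0.712, the share from 51.7% to 63.9% for UCC2003 and 60.7% to 72.2% for TadA mutant, and list calls from 13 to 18. In the gene-level table UCC2003 against GF ran from 2 to 7 (2 without GF column 1 or 4 or UCC2003 column 4; 3 without UCC2003 column 1 or 3), TadA mutant against GF from 0 to 1 (1 without UCC2003 column 3), UCC2003 against TadA mutant from 1 to 6 (1 without TadA mutant column 1, 2 without UCC2003 column 4, 6 without TadA mutant column 4) and CONV against GF from 35 to 58 (35 without CONV column 2 or GF column 1, 36 and 37 without GF columns 2 and 4).

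Median centring and quantile normalisation moved no count by more than 1.5 times, but of the clusters called in CONV against UCC2003 45.9% were higher, 52.9% with median centring and 60.8% with quantile normalisation. B4galnt2 lost its call in 9 of 29 alternatives in UCC2003 against GF (log2 -2.32 to -2.02, adjusted p up to 0.887) and in 7 of 29 against TadA mutant (-2.41 to -2.18, up to 0.634). Retnlb kept its call in 19 of 19 in UCC2003 against GF, UCC2003 against TadA mutant and CONV against GF. These 19 were the ordinary fit, the trend with a robust prior, array weights and each column left out. They did not include the smooth muscle or the Cpa1 and Cel covariate, or the fit without the arrays with pancreatic transcripts, so Retnlb was not tested against those. Olfr323 lost its call in 18 of 28 and Cnga1 in 7 of 19. No called value of a named gene changed sign, while 373 of 13813 values under the alternatives did without a call, B4galnt2 in TadA mutant against GF among them. On clusters 7636 values under alternatives chosen beforehand stayed on their side of the threshold, 116 became weaker and 22 stronger, under added ones 552, 32 and 2, and for gene-level genes 5339, 96 and 18.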

Other observations

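The planned lists gave the values below except where a gene-level value is named, and the fits of the gene-level table and the Cpa1 and Cel covariate were chosen after the data had been seen.

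Growth of the epithelium is the subject of the series title. The proliferation list was tested, as given above, but the lists of crypt stem cell and of growth factor genes had too few named members to test. Of crypt stem cell and Wnt target genes, Ascl2, a stem cell transcription factor gene, was at 0.74 ± 0.21 log2 units (SE) in UCC2003 against GF and 0.57 ± 0.21 in TadA mutant against GF in the gene-level table, and at 0.17 ± 0.21 in UCC2003 against TadA mutant. Ccnd1, the cyclin D1 gene, was at -0.11 ± 0.13, 0.19 ± 0.13 and -0.30 ± 0.13, and Bmi1 on clusters at 0.07 ± 0.21 in UCC2003 against GF. Of growth factor genes, Rspo3, which amplifies Wnt signals, was at 0.38 ± 0.13 and 0.30 ± 0.13 against GF, and Igf2 at -0.26 ± 0.13 and -0.71 ± 0.13. None of these passed (0 by limma over all tests). Mki67 and Lgr5 were not analysed here.

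Further lists of the gene-level table did not pass with camera. Mast cell genes were higher in UCC2003 than in GF in 3 of 3 members, with the chymase gene Cma1 at 0.59 ± 0.15 and the carboxypeptidase gene Cpa3 at 0.81 ± 0.22 (list adjusted p = 0.0561, and 0.00322 with fry). Absorptive colonocyte genes were higher in 3 of 3 (adjusted p = 0.0877, and 0.0411 with fry), with Sult1c2 at 0.72 ± 0.21. Macrophage and dendritic cell genes had an adjusted p of 0.0561 in the same comparison, and 0.00291 with fry. T and NK cell genes had 0.839 and xenobiotic metabolism and antimicrobial genes 0.900 in UCC2003 against GF.

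The smooth muscle list in UCC2003 against GF had a mean of 0.47 log2 units, and 0.42 with the Cpa1 and Cel level as a covariate, and in TadA mutant against GF 0.41 and 0.32. How much muscle layer each sample held was not tested.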
